A study of Homo sapiens with 6 samples.

How the data were processed

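BT20 is a human triple-negative breast cancer cell line, which means that it lacks the estrogen and progesterone receptors and HER2 amplification. Per the labels' protocols, the cells were reverse transfected for 72 hr with 5 nM of a negative control siRNA or of 1 of 2 siRNAs against ADAR1 (siADAR1-1 and siADAR1-2), carried by a lipid reagent. Total RNA was then isolated with a kit that keeps small RNA. Poly(A) RNA libraries were made with a KAPA mRNA kit and small RNA libraries with a NextFlex kit whose adapters carry random bases. There were 6 samples, 3 of poly(A) RNA and 3 of small RNA, with 1 sample per siRNA and assay.

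The authors deposited a table of log2 values for 58333 genes and a table of log2 values for 1884 mature microRNAs. Each table has 2 columns per sample, numbered as replicates per the file headers. The submitters' processing notes name FastQC, HISAT2, featureCounts, Salmon and the GRCh38 assembly, with no version, role or order. Which tool counted which RNA, whether strand was used, and how reads that match several places were treated are not given in the sources used here. No source names the transformation behind the log2 values either. It was inferred from the values: in every column 100% of the values correspond, within 0.05 of a read, to whole reads divided by a size factor and passed through a variance-stabilizing transformation in closed form. This scale nears log2 of the scaled reads for abundant features and is compressed near 0, so a difference understates the change of a feature with few reads. A gene with 1 read lies at 1.43 to 1.58 and a gene with 0 reads at 0.35; for microRNAs these levels are 0.85 to 1.04 and -0.04. Features with near-identical copies (pseudogenes, paralogs, repeat RNAs) and overlapping or antisense genes are uncertain, because the counting may divide or share their reads.

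The inferred reads gave the depth. The poly(A) columns held 45482892 and 43765329 reads for siControl, 55351690 and 53847489 for siADAR1-1, and 49719917 and 47472560 for siADAR1-2. The small RNA columns held 19031179 and 14978700 microRNA reads for siControl, 12226465 and 12805330 for siADAR1-1, and 12269738 and 16964008 for siADAR1-2. Intervals on read ratios are exact 95% binomial intervals and, like the floor of 3 reads over a group used where a group has 0 reads, cover counting error only.

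The following was fixed before the data were examined. The columns of a sample were averaged and counted as 1 replicate, because the labels give 1 sample per siRNA and assay. The main result is therefore a rule of size with no p-value: an expressed feature rose or fell when its mean log2 value differed from siControl by 1 or more, which is 2-fold for abundant features. Expressed means a mean level at or above the median of the features above the floor in at least 1 library, which left 21125 genes (level 3.58, about 12.5 reads; 14162 of them protein coding) and 870 microRNAs (level 2.08, about 6.17 reads). The comparisons were siADAR1-1 with siControl, siADAR1-2 with siControl, the features that changed the same way with both siRNAs, and siADAR1-1 with siADAR1-2, each for genes and for microRNAs. The difference between groups has no replicate check beyond the columns.

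As a check chosen before the data were seen, limma was fitted over the 6 columns of a table with the 3 groups in 1 model, and a Benjamini-Hochberg adjusted p of 0.05 was the threshold. Nothing in the labels says that the columns are separate cultures, so limma's p-values and standard errors cover only the spread between columns, which may be technical. Values written with ± give limma's standard error on the log2 scale. For gene lists, limma's count is given as adjusted over all expressed features and as adjusted over the list alone.

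There were 28 gene lists and 21 microRNA lists fixed before the data were examined, from general knowledge of ADAR1, of breast cancer cells and of cell types that the culture should not hold. Each list has the median difference of its expressed members and the percentile of that median among 10000 random lists of the same size matched on mean level. A further 8 gene lists were written after the values had been seen. Both siRNAs share a control, so 100 simulations without effects were run with the same sharing, with a spread set from the difference between the knockdown libraries; a version with the spread between columns was added after the data were seen.

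Genes were named by a rule fixed before the data were examined. It takes ADAR, the 12 genes with the largest rise and the 12 with the largest fall by the smaller of their 2 differences, and the 5 highest and 5 lowest differences between the siRNAs. It also takes up to 4 members of each gene list with the largest mean difference, plus members needed to show that a list is mixed. For microRNAs it takes the 8 largest rises and 8 largest falls, the 3 highest and 3 lowest differences between the siRNAs, and up to 3 members per list. Genes outside the rule, and those named because a count was 5 or fewer, were chosen after their values were seen. Gene symbols came from a table of gene identifiers, which matched 57830 of the 58333 identifiers; the other 503 are given by identifier. Coordinates are of GRCh38.p14 from RefSeq, matched by symbol.

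Other settings chosen before the data were seen were a level filter at the 25th and 75th percentile or none, centring each library on the median of expressed features, quantile normalization, thresholds of 1.5-fold and 4-fold, a linear pseudocount (18.1 for genes and 5.60 for microRNAs), the mean of a list in place of its median, limma, and leaving out each column in turn. Settings added after the data were seen were protein-coding genes alone, a requirement that both columns of an siRNA lie beyond both columns of its comparator, a separate control column for each siRNA, and limma with the column number as a block. The script was tested on simulated reads of the real tables. For genes, 100% of 97 genes changed by log2 2 with both siRNAs and 97.9% of 94 changed by 1.5 passed the size rule, as did 0.005% of 20190 unchanged genes. For microRNAs the shares were 93.1% of 29, 72.4% of 29 and 0% of 788. The spread in this test was a trimmed mean per level, which leaves out the features that vary most between columns. The shares of unchanged features are therefore not a rate of false passes in these data. The simulations from untrimmed column differences gave on average 37.0 shared rises and 36.5 shared falls among 21125 genes. For 870 microRNAs they gave 1.32 and 1.2. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Editing itself was not measured here, since it needs reads and a genome sequence, and protein, growth and invasion were not analysed here.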

Results

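ADAR1, encoded by ADAR, converts adenosine to inosine in double-stranded RNA and so keeps the cell's own RNA from being sensed as viral. The series title names growth and invasion of triple-negative breast cancer as the context, and the design lowers ADAR1 in BT20 cells with separate siRNAs. Poly(A) RNA and small RNA were each measured in 3 samples: siControl, siADAR1-1 and siADAR1-2. Each sample is given as 2 columns, averaged here as 1 replicate. Columns held 43765329 to 55351690 reads for genes and 12226465 to 19031179 for microRNAs. The lowest correlation between the columns of a sample was 0.989 for genes, above the highest between columns of different samples, 0.982. For microRNAs the ranges overlapped: the lowest correlation between the columns of a sample was 0.990, and the highest between columns of different samples was 0.992. The first principal component of the genes held 36.0% of the variance and parted siControl from both knockdowns, and the second, with 30.97%, parted the siRNAs from each other. Features rose or fell where they passed the size rule, and ± gives limma's standard error between columns.

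ADAR, the targeted gene (ENSG00000160710, chromosome 1, 154582057 to 154627997 in GRCh38.p14), was lower in all 4 knockdown columns than in both control columns. Its reads were 24965 and 28437 in siControl, 7587 and 7499 with siADAR1-1, and 7316 and 7361 with siADAR1-2. The log2 difference was -2.17 ± 0.11 with siADAR1-1, which leaves 22.2% of the control level (limma adjusted p = 5.47e-06). With siADAR1-2 it was -2.05 ± 0.11, which leaves 24.1% (limma adjusted p = 4.44e-06). The siRNAs differed from each other by -0.12 (limma adjusted p = 0.49), so no difference in knockdown was detected. The other expressed member of the family, ADARB1, a second adenosine deaminase of double-stranded RNA, had differences of -0.84 and -0.49, and the list of these 2 genes had medians of -1.51 and -1.27.

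**Figure D1:**
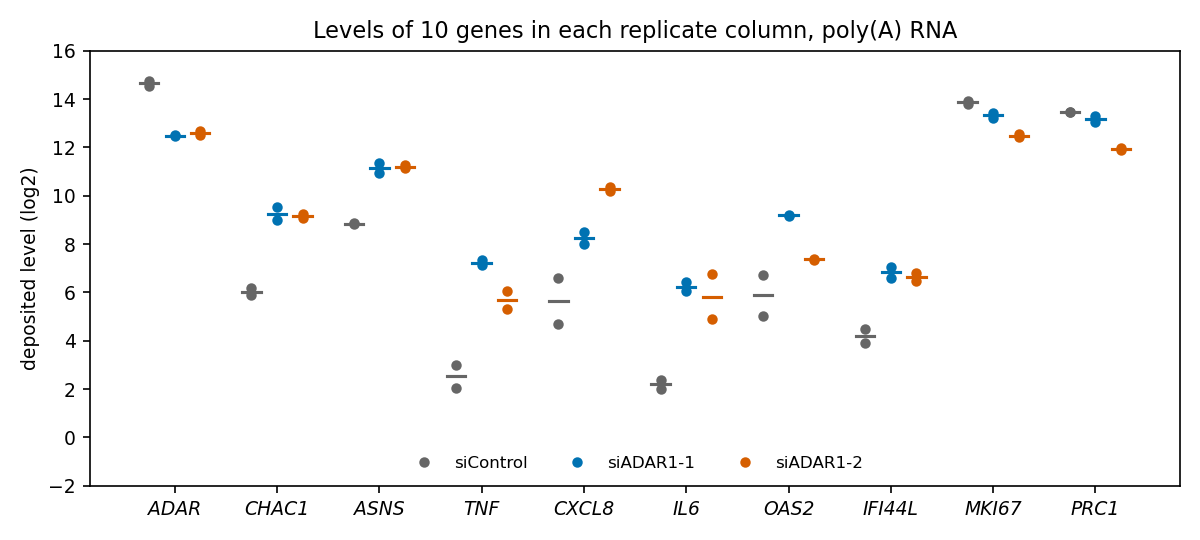
Log2 levels (vertical axes, deposited scale) of 10 genes in siControl, siADAR1-1 and siADAR1-2; dots are the 2 columns of each sample and bars their mean. ADAR was lower by 2.17 and 2.05 with the siRNAs, while CHAC1 and TNF were higher with both.

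With siADAR1-1, 14 of 19 inflammatory cytokines and NF-kB targets, 20 of 50 interferon-stimulated genes and 18 of 31 targets of the integrated stress response rose. TNF, a cytokine that activates NF-kB (chromosome 6, 31575565 to 31578336), was higher by 4.70 ± 0.39, or 26.0-fold. OAS2, an enzyme that senses double-stranded RNA and activates RNase L, was higher by 3.32 ± 0.40. CHAC1, a glutathione-degrading enzyme induced by ATF4 and CHOP (chromosome 15, 40953471 to 40956512), was higher by 3.23 ± 0.19, or 9.41-fold. SPARC, a matrix protein linked to invasion, fell by 2.87 (standard error 0.61). In all, 735 genes rose and 438 fell of 21125 expressed genes (685 and 490 after centring each library, 722 and 434 after quantile normalization; 424 and 201 stayed past 1 whichever column was left out), and limma together with the size rule called 591 and 305 (limma at any size, 2350 and 1980).

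With siADAR1-2, 8 of the 19 cytokines and NF-kB targets and 22 of the 31 stress response targets rose, and 15 of 30 cell cycle genes fell. CXCL8, a chemokine that attracts neutrophils, was higher by 4.62 ± 0.45, or 24.6-fold. CHAC1 was higher by 3.14 ± 0.19, or 8.79-fold. MYBL2, a transcription factor of proliferating cells, fell by 1.66, and MKI67, the gene of the proliferation marker Ki-67, fell by 1.39. In all, 649 genes rose and 670 fell (684 and 635 after centring, 657 and 663 after quantile normalization; 347 and 328 stayed past 1 whichever column was left out), and limma together with the size rule called 515 and 503 (limma at any size, 2158 and 2580).

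Of the 12 genes with the largest shared rises, 5 were protein-coding. IGFL1, a member of the insulin-like growth factor-like family (chromosome 19, 46229742 to 46231243), was higher by 4.72 and 3.93 (± 0.32). On the deposited scale this is 26.3-fold with siADAR1-1 and 15.2-fold with siADAR1-2. FGF21, a stress-induced metabolic hormone, had 3 control reads, and its read ratio was 48.1 (95% interval 16.2 to 236) with siADAR1-1 and 20.4 (6.69 to 101) with siADAR1-2. IL6, an inflammatory cytokine, was higher by 4.05 and 3.63 (± 0.52), from control columns at 2.01 and 2.37, levels of few reads. CXCL3, a neutrophil chemokine, had 1 control read, and its ratios were 80.0 (14.05 to 3192) and 43.7 (7.49 to 1759). RUBCNL, a regulator of autophagosome maturation, was higher by 3.34 and 3.24 (± 0.52).

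The largest shared falls in named genes included PROX1, DIRAS3, COLEC12, LVRN and GRIN1. PROX1, a homeobox transcription factor (chromosome 1, 213983151 to 214041510), fell, with differences of -2.55 and -2.50 (± 0.28). DIRAS3, an imprinted small GTPase that restrains growth, fell, with differences of -2.23 and -2.51. COLEC12, a scavenger receptor, fell, with differences of -1.94 and -2.45. LVRN, an aminopeptidase, fell, with differences of -1.75 and -1.98. GRIN1, a subunit of the NMDA receptor, fell, with differences of -2.15 and -1.73.

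Pseudogenes, small RNAs and genes without a symbol made up the rest of both ranked lists apart from CNBD2 and ADAR. EIF1AXP1, a pseudogene of a translation initiation factor, had 0 control reads and was at least 48.9-fold higher with siADAR1-1 and 46.6-fold with siADAR1-2, against a floor of 3 reads over the group. RPL23AP84, a ribosomal protein pseudogene, was at least 30.1-fold and 31.7-fold higher. For ENSG00000267601 the bounds were 40.8-fold and 34.9-fold, and for ENSG00000260537 56.2-fold and 86.8-fold, the latter with 0 and 215 reads in the siADAR1-1 columns and a difference of 0.00 without the second. ASNSP1, a pseudogene of asparagine synthetase, was higher by 4.06 and 4.14.

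Most other ranked genes rested on 1 column. RPL39P3 was higher by 4.46 and 4.88, but by 0.88 and 1.30 without siControl replicate 1. RN7SL1, the RNA of the signal recognition particle, was higher by 3.86 and 5.72, with 1966 and 0 reads in the control columns; without siControl replicate 2 the values were -1.40 and 0.46. ENSG00000265263 fell by 4.17 with siADAR1-1, or -0.99 without siADAR1-1 replicate 2; with siADAR1-2 it had 0 reads and was at least 163-fold lower. ENSG00000259185 had differences of -3.94 and -3.90, but -0.06 without siADAR1-1 replicate 2 and 0.02 without siADAR1-2 replicate 1. GNRHR2P1 had differences of -2.91 and -3.18, but 0.19 without siADAR1-1 replicate 2 and -0.35 without siADAR1-2 replicate 2. ENSG00000285330 fell, with differences of -2.95 and -2.29, the latter -0.02 without siADAR1-2 replicate 2. CNBD2, which has a cyclic nucleotide binding domain, had differences of -2.11 and -2.27, but -0.08 without siADAR1-1 replicate 2 and 0.06 without siADAR1-2 replicate 2. ENSG00000284128, which fell with differences of -1.95 and -1.90, was lower in all 4 knockdown columns than in both control columns, and was at -1.10 with siADAR1-2 without siADAR1-2 replicate 2.

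With both siRNAs 326 genes rose and 110 fell, of which 168 and 38 stayed past 1 whichever column was left out, and limma together with the size rule called 247 and 64; 10 genes passed the rule in opposite directions. The count of shared falls was 185 without siControl replicate 1 and 229 without siControl replicate 2. Both comparisons share the control. Simulations without effects that share it gave on average 161 shared rises and 162.5 shared falls (highest 202 and 199), so the observed rises lay above and the falls below; their spread came from the difference between the siRNAs, which holds real effects too. With the spread between columns, added later, the means were 37.0 and 36.5 (highest 57 and 51). Independent lists of these sizes would share 22.6 and 13.9 genes. The covariance of the differences was 0.163 across genes (r = 0.55), against 0.134 in the first simulation (r = 0.50) and 0.0483 in the second, so the differences were 0.0292 and 0.114. Genes are not independent replicates. With a separate control column for each siRNA, 267 and 100 or 279 and 95 genes were shared, and the covariance was 0.112 or 0.111. The control cannot be split with more than 1 column on each side, so part of the excess may come from the shared control.

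**Figure D2:**
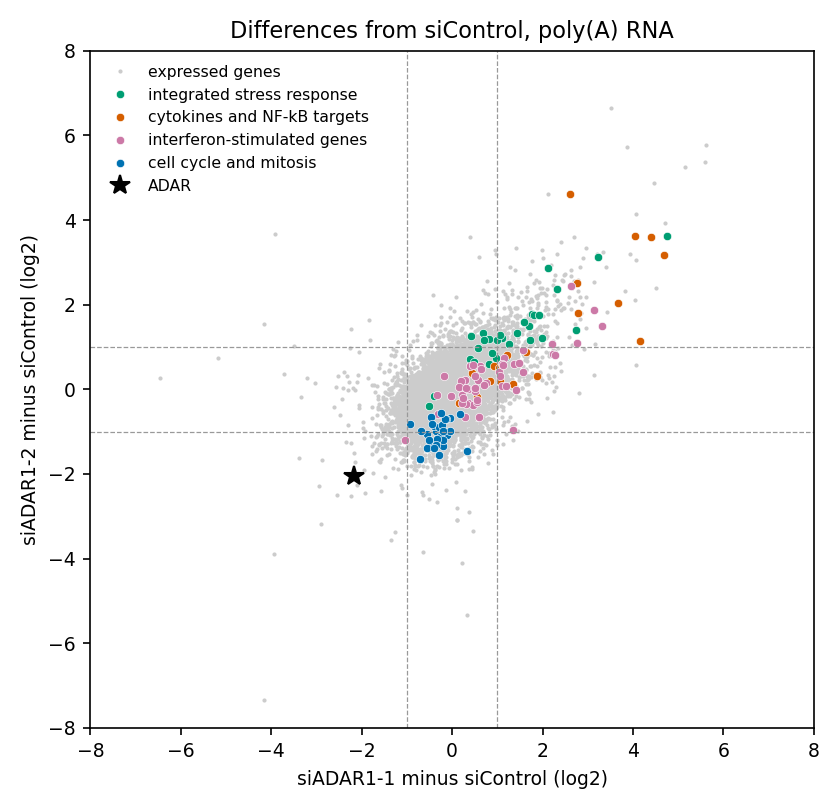
Log2 difference from siControl with siADAR1-1 (horizontal) and siADAR1-2 (vertical); each point is an expressed gene, colours mark 4 gene lists, the star is ADAR and dashed lines stand at -1 and 1. Integrated stress response genes were higher with both siRNAs (medians 1.19 and 1.21), and cell cycle genes lay lower with siADAR1-2 (-0.999) than with siADAR1-1 (-0.31).

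Targets of the integrated stress response, which ATF4 and CHOP carry out when translation is curbed, were higher to a similar size with both siRNAs. The median of 31 targets was 1.19 with siADAR1-1 and 1.21 with siADAR1-2, each at percentile 100 among random lists, and 18 and 22 of them rose, 17 with both. ASNS, which makes asparagine, was higher by 2.31 and 2.36 (± 0.13), and SLC7A11, the cystine transporter, by 2.13 and 2.86 (± 0.13). DDIT3, which encodes CHOP, was higher by 1.77 with each siRNA, while ATF4 itself had differences of 0.39 and 0.71. With siADAR1-1 limma called 28 of the targets higher and 2 lower (29 and 2 adjusted over the list alone), and with siADAR1-2 it called 29 and 1 (29 and 1 adjusted over the list alone).

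Inflammatory cytokines and NF-kB targets were higher with both siRNAs. The median of 19 expressed genes was 1.64 with siADAR1-1 and 0.80 with siADAR1-2, each at percentile 100, and 14 and 8 rose, 8 with both. CCL20, a chemokine for lymphocytes and dendritic cells, was higher by 3.67 and 2.05. CCL2, a monocyte chemokine, was higher by 4.15 and 1.14 (0.89 without siADAR1-2 replicate 1), and TNFAIP3, an inhibitor of NF-kB that NF-kB induces, by 2.79 and 1.79. TNF was higher by 3.16 with siADAR1-2, and CXCL8 by 2.61 with siADAR1-1 (1.66 without siControl replicate 1). Limma called 16 higher with siADAR1-1 (18 adjusted over the list alone) and 13 with siADAR1-2 (13 adjusted over the list alone). The median with siADAR1-2 was 0.53 without siControl replicate 1.

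Interferon-stimulated genes, which carry out the antiviral response, were higher with siADAR1-1 than with siADAR1-2. Of 50 expressed genes 20 rose and 1 fell with siADAR1-1 (median 0.59, percentile 100), and 5 rose and 1 fell with siADAR1-2 (median 0.17, percentile 99.7). The 5 that rose with both were OAS2 (1.49 with siADAR1-2), OASL, a relative of OAS2 without its activity (2.77 and 1.10), IFI44L (2.63 and 2.43), IFI44 (2.22 and 1.06) and IFI27 (3.14 and 1.86). MX1, a GTPase that blocks viruses, was higher by 2.24 with siADAR1-1 and had a difference of 0.84 with siADAR1-2. MX2, its paralog, fell with both (-1.04 and -1.21). Limma called 35 higher and 3 lower with siADAR1-1 (39 and 3 adjusted over the list alone) and 14 and 7 with siADAR1-2 (16 and 9 adjusted over the list alone). The median with siADAR1-2 was 0.04 without siControl replicate 1 and 0.28 without siADAR1-2 replicate 1; without siControl replicate 1, IFI27 was at 1.47 with siADAR1-1 and 0.20 with siADAR1-2, and OAS2 and IFI44 at 0.66 and 0.50 with siADAR1-2. OASL was at 0.76 with siADAR1-2 without siADAR1-2 replicate 1, and MX2 at -0.89 with siADAR1-1 without siADAR1-1 replicate 1, so of the shared calls IFI44L alone held without every column.

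Sensors of double-stranded RNA and their signalling genes had a median of 0.31 with siADAR1-1 (percentile 99.7) and 0.07 with siADAR1-2 (percentile 78.8) over 17 genes. With siADAR1-1 7 of them rose, among them RIGI (1.43) and IFIH1 (1.05), which encode the cytoplasmic sensors RIG-I and MDA5, and IKBKE (1.73), a kinase upstream of the interferon genes. With siADAR1-2 OAS2 and OASL rose, and limma called 9 higher and 3 lower with siADAR1-1 and 6 and 3 with siADAR1-2, counts that were 9, 3, 6 and 3 adjusted over the list alone. The median with siADAR1-1 was 0.52 without siADAR1-1 replicate 2, and IFIH1 was at 0.80 without siControl replicate 1. Type I and III interferons and their receptors had 4 expressed members with medians of 0.21 and 0.13, and IFNLR1, the lambda interferon receptor, rose with siADAR1-1 (1.17, and 0.33 with siADAR1-2). Interferon genes themselves had too few reads to be called expressed: IFNB1 had 0 and 0 reads in siControl, 3 and 5 with siADAR1-1, and 0 and 2 with siADAR1-2. CXCL10, a chemokine induced by interferon, had 0 and 1, 14 and 13, and 3 and 7 reads; both were chosen after their values were seen.

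Cell cycle and mitosis genes were lower with siADAR1-2. The median of 30 genes was -0.999 with siADAR1-2 and -0.31 with siADAR1-1, both at percentile 0; 15 genes fell with siADAR1-2 and none passed the rule with siADAR1-1. PRC1, which bundles the spindle midzone, fell by 1.55 with siADAR1-2 and had a difference of -0.30 with siADAR1-1. CDK1, the kinase that starts mitosis, fell by 1.32 with siADAR1-2 and had -0.47 with siADAR1-1. Limma called all 30 lower with siADAR1-2 (30 adjusted over the list alone) and 11 with siADAR1-1 (15 adjusted over the list alone). The median with siADAR1-1 was -0.18 without siADAR1-1 replicate 1.

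DNA replication genes followed, with a median of -0.68 with siADAR1-2 (percentile 0) and -0.19 with siADAR1-1 (percentile 0.22) over 34 genes. RRM2, a subunit of ribonucleotide reductase, fell with both (-1.11 and -1.09). POLE2, a DNA polymerase subunit, TYMS, which makes thymidylate, and GINS1 of the replicative helicase fell with siADAR1-2 (-1.23, -1.14 and -1.05, the last -0.998 without siControl replicate 2). Limma called 33 lower with siADAR1-2 (33 adjusted over the list alone) and 8 with siADAR1-1 (11 adjusted over the list alone). Replication-dependent histones, whose messages mostly lack a poly(A) tail, had medians of -0.07 and 0.45 over 12 genes. H1-4, a linker histone, rose with both (1.76 and 1.04), and H2AC6 and H4C8 rose with siADAR1-2 (1.10 and 1.05); the median with siADAR1-2 was 0.30 without siADAR1-2 replicate 2. With siADAR1-2 none of these 3 held without every column: H1-4 was at 0.81 without siADAR1-2 replicate 2, and H2AC6 and H4C8 at 0.94 and 0.91 without siControl replicate 2.

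Cholesterol synthesis genes had medians of -0.40 and -0.45 over 23 genes (both at percentile 0). None passed the rule with siADAR1-1, while INSIG1, which holds back sterol-regulated transcription, and the enzymes MSMO1 and SQLE fell with siADAR1-2 (-1.31, -1.31 and -1.20). Limma called 15 lower with siADAR1-1 (17 adjusted over the list alone) and 16 with siADAR1-2 (16 adjusted over the list alone). Genes of oxidative phosphorylation had medians of -0.29 and -0.28 over 32 genes, and SDHD and ATP5PO, subunits of complex II and of ATP synthase, fell with siADAR1-2 (-1.34 and -1.30). Limma called 13 of them lower with each siRNA (19 and 18 adjusted over the list alone). Beside this, the mitochondrially encoded share of reads was 10.3% and 9.14% in the control columns, 8.43% and 7.89% with siADAR1-1, and 8.47% and 8.08% with siADAR1-2. Ribosomal protein genes had medians of -0.33 and -0.17 over 40 genes, none passing the rule, and limma called 20 and 4 lower (32 and 1 adjusted over the list alone).

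**Figure D3:**
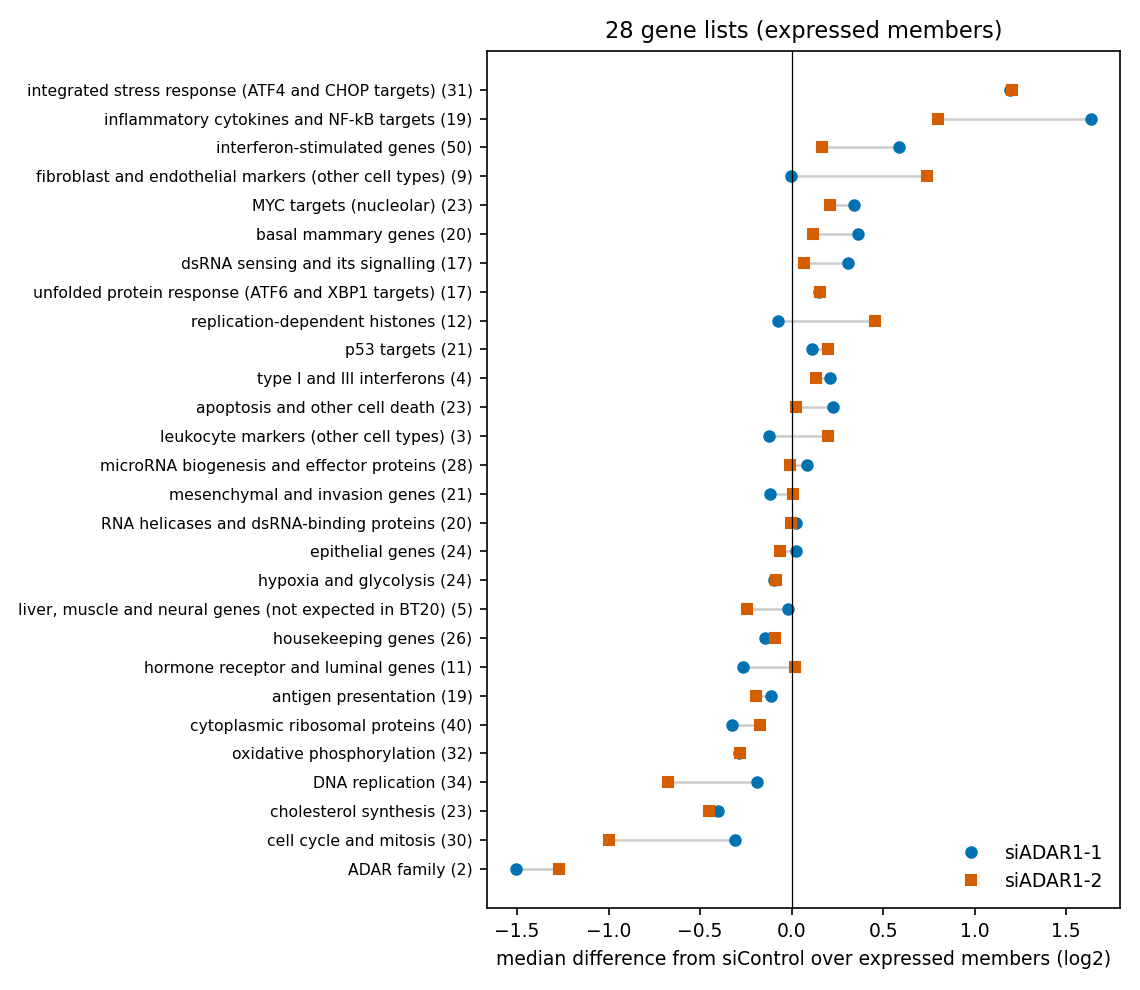
Median log2 difference from siControl (horizontal axis) over the expressed members of each of the 28 gene lists, 1 point per siRNA. The NF-kB list (1.64 and 0.80) and the integrated stress response (1.19 and 1.21) lie farthest above 0, and cell cycle genes with siADAR1-2 (-0.999) farthest below apart from the ADAR family.

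Basal mammary genes, which mark the myoepithelial-like state of many triple-negative tumours, had medians of 0.36 and 0.12 over 20 genes (means 0.40 and 0.45). KRT17, a basal keratin (1.80 and 2.51), TRIM29 (1.66 and 2.33) and CAV1, which shapes caveolae (1.28 and 1.91), rose with both, and KRT16 (1.78) and CAV2 (1.00) with siADAR1-2; without siADAR1-1 replicate 1 KRT17 was at 0.94 and CAV1 at 0.93, and without siADAR1-2 replicate 2 CAV2 was at 0.90. Limma called 7 higher with siADAR1-1, and 7 higher and 1 lower with siADAR1-2. Adjusted over the list alone it called 9 higher and 1 lower, and 7 higher and 1 lower. Hormone receptor and luminal genes had medians of -0.27 and 0.02 over 11 genes. SPDEF, a transcription factor of luminal cells, fell with both (-1.58 and -1.71), and ESR1, the estrogen receptor, had differences of -0.56 and -0.53. Epithelial genes had medians of 0.02 and -0.06 over 24 genes, and CLDN1, a tight junction protein, rose with both (2.40 and 1.87).

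Mesenchymal and invasion genes went both ways, with medians of -0.12 and 0.01 over 21 genes. SNAI2, a transcription factor of the epithelial-mesenchymal transition, rose with both (1.90 and 1.27, the latter 0.87 without siADAR1-2 replicate 1), and its relative SNAI1 fell with siADAR1-2 (-1.44). SPARC fell with both (-1.68 with siADAR1-2, or -0.69 without siADAR1-2 replicate 1), while VIM, the mesenchymal filament vimentin, had differences of -0.77 and -0.67. TNC (1.27) and TGFBI (1.07) rose with siADAR1-1, but were at 0.93 without siADAR1-1 replicate 1 and at 0.96 without siControl replicate 1. PLAU, the urokinase plasminogen activator, rose with siADAR1-2 (1.52), but was at 0.31 without siControl replicate 2. Limma called 4 higher and 4 lower with siADAR1-1 and 2 and 4 with siADAR1-2 (5 and 4, and 4 and 5, adjusted over the list alone).

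Markers of cells that the culture should not hold were read beside these groups. Fibroblast and endothelial markers had medians of -0.00 and 0.74 over 9 expressed genes (percentiles 50.9 and 99.98). With siADAR1-2 the median was -0.04 without siADAR1-2 replicate 1. A list of cells that the culture should not hold thus reached a percentile like that of interferon-stimulated genes with siADAR1-2 (99.7). An extreme percentile alone therefore does not show a response. CDH5, an endothelial cadherin, rose with both (1.21 and 1.70, the former 0.92 without siADAR1-1 replicate 1), while PECAM1 (-1.31) and COL6A3 (-1.15), an endothelial and a fibroblast marker, fell with siADAR1-2 but were at -0.54 and -0.62 without siADAR1-2 replicate 2 and without siControl replicate 1. Leukocyte markers had 3 of 15 members expressed (medians -0.13 and 0.20), and liver, muscle and neural genes 5 of 12 (medians -0.02 and -0.25), none of them passing the rule.

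Lists of stress, growth and cell death were tested too. Targets of the unfolded protein response had medians of 0.15 and 0.15 over 17 genes, with HERPUD1, a factor of protein degradation at the endoplasmic reticulum, rising with both (1.03 and 1.16, the former 0.93 without siADAR1-1 replicate 1). Targets of p53 had medians of 0.11 and 0.20 over 21 genes; GDF15, a stress cytokine also on the integrated stress response list, rose with both (2.00 and 1.22) and PMAIP1, the cell death gene NOXA, with siADAR1-1 (1.07). Cell death genes had medians of 0.22 and 0.02 over 23 genes, with GSDME, a pore-forming gasdermin, rising with siADAR1-1 (1.30). Nucleolar MYC targets had medians of 0.34 and 0.21 over 23 genes (percentiles 100 and 99.7), with MYC (1.05) and ODC1 (1.01) rising with siADAR1-1, the latter at 0.98 after centring each library; MYC was at 0.997 without siControl replicate 1 and ODC1 at 0.90 without siADAR1-1 replicate 1. Limma called 15 MYC targets higher and 2 lower with siADAR1-1 and 9 and 1 with siADAR1-2 (15 and 2, and 10 and 2, adjusted over the list alone).

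Hypoxia and glycolysis genes had medians of -0.10 and -0.09 over 24 genes; EGLN3 (1.65) and ADM (1.22) rose with siADAR1-1, while the aldolases ALDOA (-1.67) and ALDOC (-1.60) fell and ANKRD37 rose (1.03, or 0.89 without siControl replicate 2) with siADAR1-2. Antigen presentation genes had medians of -0.11 and -0.20 over 19 genes. TAP1, the peptide transporter, and NLRC5 rose with siADAR1-1 (1.48 and 1.00), HLA-DRA and CD74 of the class II pathway fell with it (-1.21 and -1.12), and CIITA, the class II transactivator, fell with siADAR1-2 (-1.39). Without 1 column, NLRC5 was at 0.78 (siControl replicate 1), CD74 at -0.80 (siADAR1-1 replicate 1) and CIITA at -0.94 (siADAR1-2 replicate 1). Proteins that make or use microRNAs had medians of 0.08 and -0.01 over 28 genes, none passing the rule, and DICER1 had differences of -0.62 and -0.86. RNA helicases and proteins that bind double-stranded RNA had medians of 0.02 and -0.00 over 20 genes; STAU1 fell (-1.53) and CDKN2AIP rose (1.87) with siADAR1-1, and ADAR is a member. Housekeeping genes had medians of -0.15 and -0.09 over 26 genes, none passing the rule.

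The comparison of the siRNAs with each other does not use the control. Relative to siADAR1-2, siADAR1-1 had higher NF-kB targets (94.7% of members), higher interferon-stimulated genes (90% of members) and higher cell cycle genes (median 0.74). NRAD1, a long non-coding RNA, was higher with siADAR1-1 than with siADAR1-2 by 3.50 ± 0.31, and rose with siADAR1-1 alone (4.07; 0.58 with siADAR1-2). CXCL8 was lower with siADAR1-1 than with siADAR1-2, with a difference of -2.02 (limma adjusted p = 0.00882). The other genes at the ends of this comparison were pseudogenes, non-coding RNAs and genes without a symbol. ENSG00000270103 had 0 reads with siADAR1-2 and was at least 51.2-fold higher with siADAR1-1, while CDC27P3, ENSG00000260482 and LINC02203 were higher by 4.34, 3.81 and 3.28. Each of these 3 had 0 reads in 1 siADAR1-2 column (0 and 44, 77 and 0, and 16 and 0), and without that column the differences were 1.81, 0.99 and 1.49. RPL41P1, ENSG00000261063, ENSG00000259976 and RNU11, a spliceosomal RNA, had 0 reads with siADAR1-1 and were at least 232-fold, 116-fold, 67.5-fold and 56.8-fold lower with it. SPECC1L-ADORA2A, a read-through gene, was lower with siADAR1-1, with a difference of -4.51 and with 0 and 279 reads in its columns, or -0.82 without siADAR1-1 replicate 1. In all, 671 genes were higher and 448 lower with siADAR1-1, and limma together with the size rule called 524 and 324. The genes were 579 and 533 after centring each library and 648 and 459 after quantile normalization, and 345 and 193 stayed past 1 whichever column was left out.

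Among microRNAs the largest change was a fall of miR-4454, a sequence close to a transfer RNA, with both siRNAs. It had 1227 and 1841 reads in siControl, 39 and 34 with siADAR1-1, and 30 and 39 with siADAR1-2, a difference of -4.88 and -5.07 (± 0.31; limma adjusted p = 1.89e-10 and 8.64e-11). Of the microRNAs that rose with both, miR-27a-5p, the minor strand of miR-27a, had the most reads: 9992 and 5751 in siControl, 16629 and 13113 with siADAR1-1, and 13715 and 13229 with siADAR1-2. Its differences were 1.32 and 1.07 (± 0.21; limma adjusted p = 0.000962 and 0.00482), and the latter was 0.81 without siControl replicate 2 and 0.83 without siADAR1-2 replicate 1. Its neighbour miR-23a-5p was higher by 1.21 and 1.24.

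The other shared rises rested on few reads. They were miR-4485-3p (2.16 and 1.69, from 57 control reads), miR-1248 (1.99 and 1.99, from 6), miR-4488 (1.57 and 2.48, from 133), miR-3960 (1.23 and 2.03, from 19) and miR-6087 (1.22 and 1.94, from 20). With them rose miR-4301 (1.19 and 3.10, from 125), miR-4690-3p (1.18 and 1.63, from 7), miR-4284 (1.18 and 1.13, from 13) and miR-3609 (1.04 and 1.31, from 21). The second shared fall was miR-6762-3p (-1.07 and -1.02, from 31; limma adjusted p = 0.594 and 0.613). Next in rank but past the rule with at most 1 siRNA were miR-4511 (-0.94 and -1.18), miR-6837-3p (-1.66 and -0.88), miR-4689 (-0.87 and -0.99), miR-671-5p (-0.81 and -0.83) and miR-1303 (-0.78 and -0.91).

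**Figure D4:**
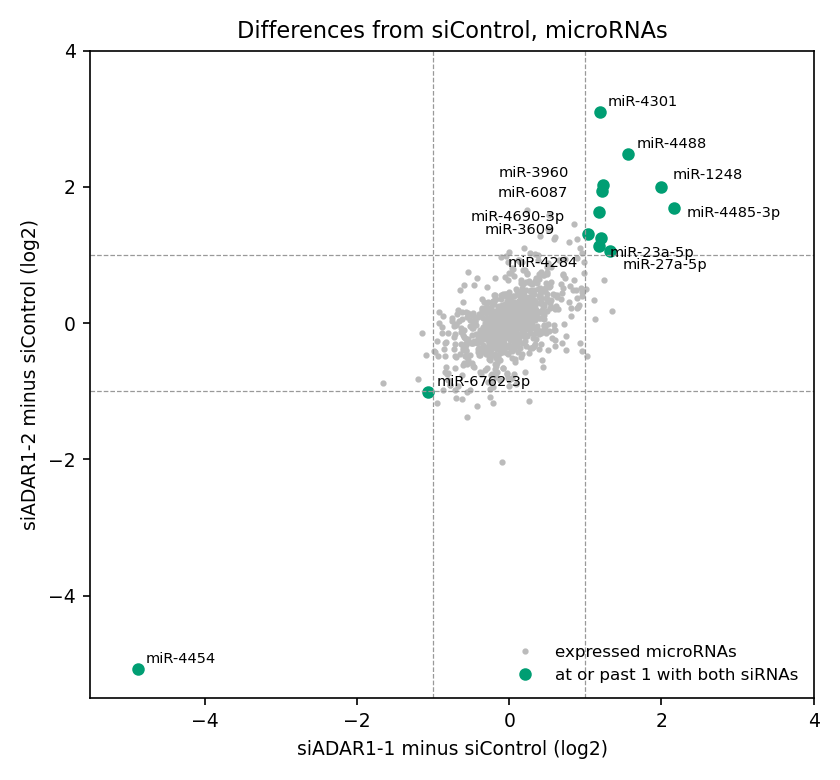
Log2 difference from siControl with siADAR1-1 (horizontal) and siADAR1-2 (vertical) for 870 expressed microRNAs; labelled points are the 13 that passed 1 with both siRNAs and dashed lines stand at -1 and 1. miR-4454 lies alone at -4.88 and -5.07.

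With siADAR1-1 17 microRNAs rose and 6 fell, and limma together with the size rule called 6 and 1. The total of 23 was 52 without siControl replicate 1, 56 without siControl replicate 2, 39 without siADAR1-1 replicate 1 and 59 without siADAR1-1 replicate 2. With siADAR1-2 26 rose and 12 fell, or 22 and 16 after centring each library (68.4% and 57.9% higher), and limma together with the size rule called 12 and 3. The total of 38 was 61 without siControl replicate 1 and 68 without siADAR1-2 replicate 2. With both, 11 rose and 2 fell, and none passed the rule in opposite directions. Without siControl replicate 1 the counts were 20 and 4, and without siControl replicate 2 they were 13 and 10. They were 20 and 21 with no level filter, 20 and 12 with the filter at the 25th percentile, and 5 and 1 at the 75th. At 1.5-fold they were 27 and 20. The excess of rises thus depends on a control column, on the level filter and on the threshold. Of the 11 and 2, 5 and 1 stayed past 1 whichever column was left out, as did 10 of the 23 with siADAR1-1 and 14 of the 38 with siADAR1-2. Limma together with the size rule called miR-1248, miR-4485-3p, miR-4488 and miR-27a-5p higher and miR-4454 lower with both. Simulations without effects gave 2.59 shared rises and 2.19 shared falls on average (highest 8 and 7), and 1.32 and 1.2 with the spread between columns (highest 6 and 5). Independent lists would share 0.508 and 0.0828. The covariance across microRNAs was 0.141 (r = 0.63), against 0.0849 (r = 0.50) and 0.0712 in the simulations, so the differences were 0.0559 and 0.0696. With separate control columns 8 and 1 or 8 and 2 were shared, and the covariance was 0.0586 or 0.0755.

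Between the siRNAs 9 microRNAs were higher and 13 lower with siADAR1-1 (40.9% higher; 59.1% after centring each library and 57.9% after quantile normalization). The highest were miR-548e-3p (1.94), miR-3942-5p (1.51) and miR-4640-5p (1.41), and the lowest miR-4301 (-1.91), miR-4497 (-1.43) and miR-6784-3p (-1.30). Limma together with the size rule called miR-548e-3p and miR-92a-1-5p (1.06) higher and miR-4301 and miR-4497 lower, with adjusted p of 0.00216, 0.0225, 0.0225 and 0.0225. Of the 22, 5 stayed past 1 whichever column was left out, and the total was 36 without siADAR1-1 replicate 1, 50 without siADAR1-1 replicate 2, 40 without siADAR1-2 replicate 1 and 60 without siADAR1-2 replicate 2.

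MicroRNA lists were read in the same way as gene lists. The medians with siADAR1-1 and siADAR1-2 were 0.03 and 0.05 for the let-7 family (18 members), which restrains growth, and -0.12 and -0.11 for the miR-200 family (9), which guards the epithelial state. They were 0.07 and -0.29 for the miR-34 family (3), 0.21 and 0.13 for miR-221 and miR-222 (4 strands), 0.05 and -0.20 for the miR-29 family (7), 0.17 and 0.10 for the miR-30 family (11; percentiles 98.4 and 89.8), 0.41 and 0.28 for the miR-181 family (7; percentiles 99.2 and 97.4), and 0.10 and 0.11 for miR-143-3p, the expressed member of the group of miR-143 and miR-145. None of these members passed the rule, and the same held for miR-203 and miR-205 of epithelium (4; -0.03 and -0.29, percentiles 46.9 and 1.68), for miR-21, miR-10b and miR-31 and their kin (7; -0.21 and -0.03, percentiles 2.11 and 28.7), for miR-210 of hypoxia (2; 0.04 and 0.11), for the chromosome 19 cluster (6; 0.11 and 0.01), and for microRNAs of muscle, blood, endothelium and brain (9; 0.05 and 0.05). In the cluster of miR-183, miR-96 and miR-182 (5; 0.04 and 0.11) none passed it either, and miR-182-5p had differences of 0.04 and -0.80 (limma adjusted p = 0.987 and 0.00901). Percentiles are given where a list lay among the lowest or highest 2.5% of random lists with either siRNA, and they are not adjusted for the number of lists.

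The other families had members that passed the rule. The miR-17~92 cluster and its paralogues, which promote proliferation, had medians of -0.03 and -0.27 over 26 members (percentiles 25.6 and 0.01). Between the siRNAs the median was 0.38 (percentile 100), with 76.9% of members higher with siADAR1-1; miR-20a-5p (-1.17) and miR-106a-5p (-1.01) fell with siADAR1-2 and miR-92a-1-5p rose with siADAR1-1 (1.12). In the miR-15/16 family (14; 0.04 and -0.13) miR-503-3p (1.35) and miR-424-3p (1.12) rose with siADAR1-1. In the miR-232724 clusters (11; 0.12 and 0.10) miR-27a-5p and miR-23a-5p rose with both. The miR-146 and miR-155 list, tied to NF-kB and interferon, had medians of -0.62 and -0.66 over 4 members (percentiles 0.33 and 0.205), or -0.28 and -0.21 without siControl replicate 1 and -0.24 with siADAR1-2 without siADAR1-2 replicate 1. Its member miR-155-5p fell by 1.19 with siADAR1-1, with 231 and 40 control reads, and was at -0.13 without siControl replicate 1. In the miR-99/100 and miR-125 family (8; -0.05 and 0.14) miR-125b-1-3p rose with siADAR1-2 (1.38), and in the 14q32 cluster (9; 0.41 and 0.23, percentiles 98.6 and 85.7) miR-543 did (1.28). The 14q32 median with siADAR1-1 was -0.19 without siControl replicate 2, -0.14 without siADAR1-1 replicate 1, 0.67 without siControl replicate 1 and 0.69 without siADAR1-1 replicate 2. MicroRNAs whose primary transcripts are described as edited had medians of 0.04 and 0.06 over 26 members, with miR-27a-5p alone passing the rule. Limma called, with siADAR1-1 and siADAR1-2, 1 and 2 members of the miR-17~92 list (1 and 5 adjusted over the list alone), 1 of miR-15/16 with siADAR1-1 (3), 1 and 2 of miR-232724 (2 and 2) and 1 and 1 of the edited list (2 and 2).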

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

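Among the tests given here, those of a neighbouring gene and of fragments of other small RNAs were chosen before their results were seen, and the others after. The results listed first were picked because limma's test of the difference between the siRNAs passed an adjusted p of 0.05, which covers only the spread between columns. Among listed genes, siADAR1-1 lay above siADAR1-2 for OAS2 (1.83), OASL (1.66), TNF (1.53), PRC1 (1.25), ALDOA (1.22), CDKN2AIP (1.14), ATP5PO (1.11) and SDHD (1.05), and below it for STAU1 (-1.34) and CXCL8 (-2.02). STAU1, which binds double-stranded RNA and takes part in messenger RNA decay, fell by 1.53 with siADAR1-1 and had a difference of -0.19 with siADAR1-2. Among non-coding genes, siADAR1-1 lay above for ENSG00000270103 (5.67), CDC27P3 (4.34), NRAD1 (3.50) and LINC02203 (3.28). It lay below for RNU11 (-5.72), ENSG00000259976 (-5.93), ENSG00000261063 (-6.72) and RPL41P1 (-7.61). The last 4 had 0 reads with siADAR1-1, and ENSG00000270103 had 0 with siADAR1-2, so the size of these 5 depends on the transformation. CDC27P3 and LINC02203 had 0 reads in 1 siADAR1-2 column and were at 1.81 and 1.49 without it. RPL41P1 had 0 and 298 reads in the control columns. Among microRNAs, the difference was 1.94 for miR-548e-3p, -1.43 for miR-4497 and -1.91 for miR-4301.

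No difference between the siRNAs in the ADAR message was detected, and ADAR1 protein was not analysed here. Yet cell cycle genes were lower with siADAR1-2 while interferon-stimulated and NF-kB genes were higher with siADAR1-1. A stronger knockdown by 1 siRNA would move all of these lists further with the same siRNA. The smaller of the opposed margins was 0.42 (95% interval 0.23 to 0.70), which argues against it for these lists. The margins are the pattern itself and were seen before the rule was written, so they add no separate test. Scaling of the libraries is argued against as well: the cell cycle lists still differed by 0.68 (0.56 to 0.80) after centring, the lower of the values under both scalings. Both intervals resample the genes of a list with 1 sample per siRNA, so they do not cover variation between transfections. Effects of an siRNA sequence on other messages could account for the split and cannot be told apart from it here: of the protein-coding genes past 1 with 1 siRNA and within 0.25 of the control with the other, 46.3% of 121 (37.6 to 55.1) fell with siADAR1-1 and 78.3% of 180 (71.8 to 83.7) with siADAR1-2. Of the 180 genes 4 are on the cell cycle or replication lists, and the share was 77.8% without them. The siRNA sequences and the 3′ untranslated regions were not used here, and a difference in timing or in how cells took the transfection stays open and untested.

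Of the 24 genes with the largest shared changes, 12 lacked a protein-coding annotation (7 of 12 rises and 5 of 12 falls), and their median SD between columns was 2.36, against 0.502 in the ranked protein-coding genes. Over all 160 such genes that passed 1 with both siRNAs the median SD was 0.459, against 0.432 in protein-coding genes matched on level, a ratio of 1.06 (95% interval 0.848 to 1.29). Pseudogenes that follow the parent gene are argued against as the general cause, since 16.1% of 31 (7.09 to 32.6) had a parent that moved 1.5-fold or more the same way. Some of the 31 share a parent, NF1 and KRT16 among them, and these limits count them as independent. For scale, of 21125 expressed genes 956 rose and 653 fell 1.5-fold or more with both siRNAs. The 5 pseudogenes whose parent moved the same way, ASNSP1 among them, may therefore still follow it. Reads shared with near-identical genes and divided unevenly may still contribute, because the interval of that ratio leaves room, and a split that is wrong in the same way in every column was not tested. Read-through from a neighbour cannot be told apart either: 28.6% of 35 pseudogenes (16.3 to 45.1) had a gene within 20000 bases that moved with them. The share among other genes was not computed, and NEK2P2 and NF1P6 each count as the neighbour of the other.

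The microRNAs that moved with both siRNAs were mostly rare. Counting noise alone is argued against: 100 simulations without effects gave 0.26 such microRNAs on average (lowest 0, highest 2), against the 13 seen. They hold no other spread. With the spread between columns, simulations gave 1.32 rises and 1.2 falls on average (highest 6 and 5). With that between the siRNAs they gave 2.59 and 2.19 (highest 8 and 7). The 11 rises lay above these and the 2 falls within them, and 6 of the 13 stayed past 1 whichever column was left out. The test of counting noise replaced an earlier one on the read ratios of the 13 themselves. In that earlier test all 13 excluded 1, but they had been picked for size. A general rise of the minor strand of hairpins is argued against by a median difference of 0.00597 between strands (-0.05 to 0.05, 199 hairpins). Fragments of other small RNAs remain a candidate explanation that cannot be told apart here. Of 12 with a known place, 1, or 8.33% (0.211 to 38.5), overlapped another small RNA (miR-1248, inside SNORA81), against 0.708% of 847 others. The number is small, and the overlap cannot see fragments of RNAs encoded elsewhere. For example, miR-4454, whose sequence is close to a transfer RNA, counted as not overlapping. Reads of the transfected siRNAs themselves were not looked for, as no siRNA sequence was used here, and an effect of ADAR1 on microRNA processing stays open and untested.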

How the results depend on the processing

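The settings of protein-coding genes alone, of both columns beyond both comparator columns, of separate control columns and of the block were chosen after the data were seen; all others were planned. Counts follow the order siADAR1-1, siADAR1-2, both siRNAs, and siADAR1-1 against siADAR1-2. For genes these were 1173, 1319, 436 and 1119. They were 2902, 3309, 1129 and 2783 with a level filter at the 25th percentile (31687 genes), 316, 392, 110 and 303 at the 75th percentile (10563 genes), and 4484, 4829, 1713 and 4281 with no level filter. They were 3813, 4369, 1609 and 4037 at 1.5-fold, 176, 147, 74 and 102 at 4-fold, and 600, 692, 222 and 552 with the linear pseudocount. With protein-coding genes alone, siADAR1-1, siADAR1-2 and both gave 755, 862 and 276. These shifts follow from fewer or more genes tested, a stricter or looser threshold, and smaller differences after a pseudocount. Leaving out 1 column that a comparison uses gave 1228 to 1554, 1449 to 1731, 410 to 633 and 1288 to 1405 genes, higher in every case but the shared count; a lone column has more spread than a mean.

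For microRNAs the counts were 23, 38, 13 and 22. They were 103, 100, 32 and 107 at the 25th percentile (1304 microRNAs), 9, 15, 6 and 8 at the 75th percentile (435 microRNAs), and 144, 140, 41 and 149 with no level filter. They were 132, 139, 47 and 132 at 1.5-fold, 2, 5, 1 and 0 at 4-fold, and 12, 16, 7 and 5 with the linear pseudocount. Limma together with the size rule gave 7, 15, 5 and 4. Leaving out 1 column in use gave 39 to 59, 53 to 68, 12 to 24 and 36 to 60. MicroRNA counts thus depend on which columns are used more than gene counts do. The microRNA filter lies at about 6.17 reads, but whether few reads are the reason was not tested.

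The deviations of same-numbered columns from the mean of the sample correlated at 0.073, 0.018 and 0.032 across genes and at 0.147, 0.073 and 0.182 across microRNAs. All were above 0, so each column went best with its own number. Components with 12.3% of the variance of genes and 21.5% of that of microRNAs parted the numbers. The correlations are low, but same-numbered columns may share a source of spread. The limma p-values and standard errors given above do not take it out. With the number as a replicate block, limma together with the size rule gave 993, 1112, 351 and 940 genes and 9, 15, 6 and 4 microRNAs, against 896, 1018, 311 and 848 genes without it.

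ADAR stayed between -2.29 and -2.05 with siADAR1-1 and between -2.17 and -1.93 with siADAR1-2 when 1 column was left out. Of the leading lists, the integrated stress response kept its medians within 1.03 to 1.36 and 1.09 to 1.35. The mean in place of the median gave 0.88 for interferon-stimulated genes with siADAR1-1 and 2.11 and 1.37 for NF-kB targets. Leaving out 1 column gave 0.54 to 0.70 and 0.044 to 0.28 for interferon-stimulated genes, 1.28 to 1.99 and 0.53 to 1.02 for NF-kB targets, and -0.45 to -0.18 and -1.19 to -0.92 for cell cycle genes; the cause was not tested.

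Leaving out 1 column that a value rests on turned 9 of 2072 values of the report around. A further 88 moved by more than the spread between columns. These counts do not measure how stable single genes or microRNAs were. Leaving out 1 of 2 columns shifts their mean by no more than that spread, so they could not count as moved. Only values past the size rule, or lists among the lowest or highest 2.5%, could count as turned around. Of the 436 shared gene calls, 206 stayed past 1 whichever column was left out. With siADAR1-1, RN7SL1 ranged from -1.40 (without siControl replicate 2) to 9.12, GNRHR2P1 from -6.01 to 0.19 (without siADAR1-1 replicate 2), and SPECC1L-ADORA2A from -7.19 to 0.19 (without siADAR1-1 replicate 1). With siADAR1-2, ENSG00000259185 ranged from -7.83 to 0.025 (without siADAR1-2 replicate 1) and CNBD2 from -4.60 to 0.065 (without siADAR1-2 replicate 2). RPL41P1 ranged from -0.25 (without siControl replicate 1) to 7.61, and the fibroblast and endothelial list from -0.041 (without siADAR1-2 replicate 1) to 0.74. The 14q32 list with siADAR1-1 ranged from -0.19 (without siControl replicate 2) to 0.69, with -0.14 without siADAR1-1 replicate 1. The genes of the observations are not in the 2072 values. Of them, CDSN with siADAR1-1 turned around, to 0.50. Under the other settings none of 1602 values turned around and 176 moved; the cause was not tested.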

Other observations

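All gene lists in this part other than those of the report were written after the values were seen; the test of host genes was fixed before. Immediate-early and AP-1 genes, which answer growth signals and stress within minutes, had medians of 0.67 with siADAR1-1 and 0.42 with siADAR1-2 over 31 genes, and 9 rose and 1 fell with each siRNA, 7 of the rises with both. DUSP1, a phosphatase that shuts off MAP kinases (2.77 and 2.59), NR4A3, an orphan nuclear receptor (2.95 and 2.19, the latter 1.44 without siADAR1-2 replicate 1), KLF4 (1.85 and 2.20), CCN1, a matrix protein regulated by YAP (2.48 and 1.92), and JUN (1.42 and 1.48) rose with both. CCN2, a relative of CCN1, had differences of -1.19 and 1.13 from control reads of 62 and 12 (limma adjusted p = 0.185 and 0.204). They were -0.14 with siADAR1-1 without siControl replicate 1 and 0.072 with siADAR1-2 without siControl replicate 2, so both rest on the control columns; the difference between the siRNAs, which does not use them, was -2.32. EGR3 fell by 1.56 with siADAR1-2. EDN1, the vasoactive peptide endothelin (2.91 and 3.10), GADD45A, a growth arrest gene (2.72 and 2.45), and CREB5, a transcription factor (3.93 and 3.20), were other protein-coding genes that rose with both. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto transfer RNA, had medians of 0.23 and 0.28 over 20 genes; GARS1 (1.33 and 1.58) and CARS1 (1.05 and 1.29, the former 0.93 without siADAR1-1 replicate 1) rose with both, and WARS1 (1.17) and MARS1 (1.14) with siADAR1-2.

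Metallothioneins, which bind zinc and copper, had medians of -0.23 with siADAR1-1 and 1.33 with siADAR1-2 over 4 genes, and MT1F (1.86), MT1E (1.37) and MT1X (1.29) rose with siADAR1-2. Epidermal differentiation genes had medians of 0.21 and 0.04 over 16 genes: KRT13 rose with siADAR1-1 (1.24, or 0.87 without siADAR1-1 replicate 1), PI3, the elastase inhibitor elafin, rose with siADAR1-2 (2.01), and CDSN fell by 2.53 with siADAR1-1, with 108 and 0 reads in its columns, and was at 0.50 without siADAR1-1 replicate 2. Mitochondrially encoded messages had medians of -0.37 and -0.41 over 13 genes, none past the size rule. Autophagy and lysosome genes had medians of 0.10 and 0.14 over 21 genes, with CTSB, the protease cathepsin B, lower with siADAR1-2 (-1.06, or -0.95 without siADAR1-2 replicate 1). Heat shock proteins (medians 0.03 and -0.02, 12 genes) and proteasome subunits (0.06 and -0.03, 31 genes) had no member past the rule. BIN1, a membrane-bending protein that interacts with MYC, fell by 2.57 with siADAR1-1 (807 and 802 reads against 3772 and 3775) and had a difference of 0.06 with siADAR1-2. GASK1B, a Golgi protein (0.39 and 3.59), KITLG, the ligand of the receptor KIT (-0.43 and 2.23), and VTCN1, an inhibitory ligand of T cells (0.45 and -1.84), differed between the siRNAs in the other direction or with the other siRNA.

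Whether the interferon and stress responses lie in the same cells was not tested, since medians of libraries do not show it. The ratio of the medians with siADAR1-1 and siADAR1-2 was 3.50 for interferon-stimulated genes and 0.988 for the integrated stress response. No use is made of these ratios, because the first divides by a median of 0.17, which was 0.044 without siControl replicate 1.

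A microRNA inside a host gene could follow the transcription of that gene. Across 44 host genes with 68 pairs, the mean difference of the host and of its microRNAs had a Spearman rho of 0.19 (95% interval -0.12 to 0.44; permutation p = 0.226, 0.452 after Benjamini-Hochberg adjustment over both correlations) and a Pearson r of 0.01 (permutation p = 0.931). Without ARRB1 and PDE2A, the hosts whose own differences lay farthest from the median, r was 0.00 and rho 0.19. EIF4A2 was kept, although its microRNA, miR-1248, had the largest difference of all microRNAs in the pairs (1.99, against -0.37 for the host). The Pearson r was not computed without it, so r near 0 may rest on this pair. Host genes are not independent replicates, and the interval leaves room for both a weak link and none.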
